A study of Homo sapiens and Mus musculus with 10 samples.

How the data were processed

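Total RNA had been extracted with Trizol and sequenced from Illumina libraries of 10 samples, 5 of the human line HCT116 and 5 of the mouse line CT26. Each line has a single wild-type library and 2 libraries for each perturbed group, numbered 1 and 2 in the labels: NIPBL knockout and SMC1A knockdown in HCT116, Nipbl knockout and Stag2 knockout in CT26. The labels do not say whether 1 and 2 are separate cultures or clones. Every p-value below therefore holds only for these samples, whose differences may be technical. The p-values of single genes measure the spread between these samples, and those of gene lists do not.

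The deposited files are 2 tables of protein-coding genes, 1 per cell line, and the authors' values in them are a signal, a normalized expression per gene whose kind (TPM or FPKM) is not given in the sources used here. The submitters' processing notes name STAR and RSEM, with no versions and no genome build. The values are not whole numbers, and the columns share 98.5 to 100% of their values of 1000 or more in HCT116 and 100% in CT26, as they would after quantile normalization, a step no source used here records. Column totals are 909584 to 921644 in HCT116 and 795059 to 804885 in CT26. Sequencing depth is not given in the sources used here and no counts can be recovered, so the counting precision of each library is unknown. The plan made before the data were examined was a test on counts. Since the files hold another unit, the plan's second choice for normalized values was used throughout.

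The HCT116 table holds 22339 rows for 20068 symbols and the one for CT26 holds 21963 rows for 21938 symbols. Rows with a repeated symbol (2271 in HCT116, mostly copies on alternate sequences, and 25 in CT26) were summed, a choice made after the files were seen, with 1 row per symbol as an alternative. In 25 HCT116 and 24 CT26 symbols a spreadsheet had turned the name into a date, and these were kept as they stand. Genes with a mean of at least 1 over the 5 libraries of a line were tested, 12211 in HCT116 and 10510 in CT26.

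Log2 of the value plus 1 was fitted with limma 3.58.1 (limma-trend) in R 4.3.3, with 3 groups per cell line, 2 residual degrees of freedom before moderation and 6.05 (HCT116) or 6.64 (CT26) after it. The lone wild-type library is assumed to vary like the perturbed groups. P-values were adjusted by the Benjamini-Hochberg method and a gene counts as called at an adjusted p under 0.05. Each perturbed group was compared with wild type and with the other perturbed group of its line. Log2 fold changes are given with their standard error, and values of a group as mean ± SD. A fold change of a gene near 0 depends on the 1 added before the logarithm.

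Gene lists were fixed before the data were examined, and a list was tested where at least 5 members were measured: 22 lists in HCT116 and 24 in CT26. They were tested with camera from limma (preset correlation 0.01, Benjamini-Hochberg over the lists), with the correlation estimated per list and with fry as alternatives. Camera compares the members of a list with all other genes. At the preset correlation members count as nearly independent, so a small p-value there does not measure the spread between libraries. Within a list, members were also adjusted over the list alone. Markers of leukocytes, fibroblasts and endothelial cells were among the lists.

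The rule for the genes to name, also fixed before the data were examined, takes the perturbed genes, called members of the cohesin list, the called genes with the largest fold changes, up to 2 members per direction of each list that pass when adjusted over the list alone and genes called in both NIPBL knockouts. Where fewer than 5 genes pass in a comparison, it takes the 5 with the smallest p. Genes named outside this rule were chosen after their values were seen, and they are given as values of single libraries.

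Both perturbed groups of a line are compared with the same wild-type library, so their fold changes correlate even with no effect. The correlation and covariance across genes and the numbers of genes shared at an unadjusted p under 0.05 were set beside 100 simulations of unchanged groups against 1 shared wild type. Between the lines, genes were matched by symbol with capital letters ignored, which is no curated ortholog map, and the difference of the NIPBL knockout effect between the lines was tested with limma on 8898 genes over all 10 libraries, with 4 residual degrees of freedom. Human gene positions are those of GENCODE 29 (GRCh38), an annotation chosen here. Windows of 20 Mb with at least 20 genes of mean value 5 or more were compared between HCT116 libraries. Mouse positions were not analysed here.

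The procedure was tested on simulated data with 200 changed genes and spreads drawn from the fitted prior. Of 66 genes changed by 4 on the log2 scale, 53 to 63 were called in the 6 comparisons, of 67 changed by 2, 14 to 47, and of 67 changed by 1, 0 to 2, with 2.86 to 6.02% of the calls false. With the moderated spreads of the data instead, 61 to 65, 39 to 65 and 3 to 19 were called, with 7.5 to 16.9% of the calls false. A list shifted by 1 was found by camera with the preset correlation in all 6 comparisons (adjusted p = 5.34e-35 to 1.45e-08), with 1 unshifted list called falsely, between the Nipbl and Stag2 knockouts, and 0 in the other comparisons. With an estimated correlation it was found in 0 of the 6 (adjusted p = 0.113 to 0.921), so that alternative did not find a shift of this size, and larger shifts were not simulated. The simulated genes varied independently of each other. In the data, the test between the lines estimated a correlation of 0.82 for the interferon list and 0.68 for DNA replication. The simulation therefore cannot show how often the preset correlation calls a list of such genes falsely.

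Alternatives were a pseudocount of 0.1, no filter on low values, an added threshold of 1 on the absolute log2 fold change, only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Chosen after the data were seen were a filter at a mean of 5, median-centred libraries, quantile normalization of the tested genes, robust variance moderation and 1 row per symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. One gene that passed over its list alone between the Nipbl and Stag2 knockouts is not reported here.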

Results

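Cohesin is the ring-shaped protein complex that holds sister chromatids together and folds chromosomes into loops. NIPBL loads it onto DNA, SMC1A is one of its core subunits and STAG2 a subunit bound to the ring. Gene expression was compared between wild-type and perturbed libraries of HCT116, a human colorectal cancer line (wild type n = 1, NIPBL knockout n = 2, SMC1A knockdown n = 2), and of CT26, a mouse colon carcinoma line (wild type n = 1, Nipbl knockout n = 2, Stag2 knockout n = 2).

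Of the targeted genes, SMC1A was far lower where its label says so, Stag2 lay close to wild type, and NIPBL and Nipbl were higher. SMC1A stood at 60 in wild-type HCT116 and at 9.78 and 5.88 in the knockdown (mean 7.83 ± 2.76, n = 2, 13.1% of wild type), a log2 fold change of -2.82 ± 0.34. In the NIPBL knockout it was 45.7 and 47. NIPBL was 11.5 in wild type, 13.8 and 14.9 in the libraries labelled NIPBL knockout (mean 14.4 ± 0.785, n = 2, log2 fold change 0.30 ± 0.28) and 9.47 and 10.8 in the SMC1A knockdown. In CT26, Nipbl was 14.6 in wild type, 16.5 and 20.8 in the libraries labelled Nipbl knockout (mean 18.6 ± 3.03, n = 2, 0.32 ± 0.31) and 22.5 and 19.4 in the Stag2 knockout. Stag2 was 19.7 in wild type, 18.8 and 19.1 in the libraries labelled Stag2 knockout (mean 18.9 ± 0.233, n = 2, 96.1% of wild type) and 23.4 and 17 in the Nipbl knockout. The transcripts of NIPBL, Nipbl and Stag2 therefore do not show their knockouts, and every direction below belongs to libraries that carry these labels. SMC1A in the knockdown passed when adjusted over the list alone, that of cohesin genes (adjusted p = 0.00285), and not over all genes (adjusted p = 0.651). Without SMC1A knockdown replicate 1 it passed over all genes as well (log2 fold change -3.15, adjusted p = 0.024). No other cohesin gene was called in any comparison.

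**Figure D1:**
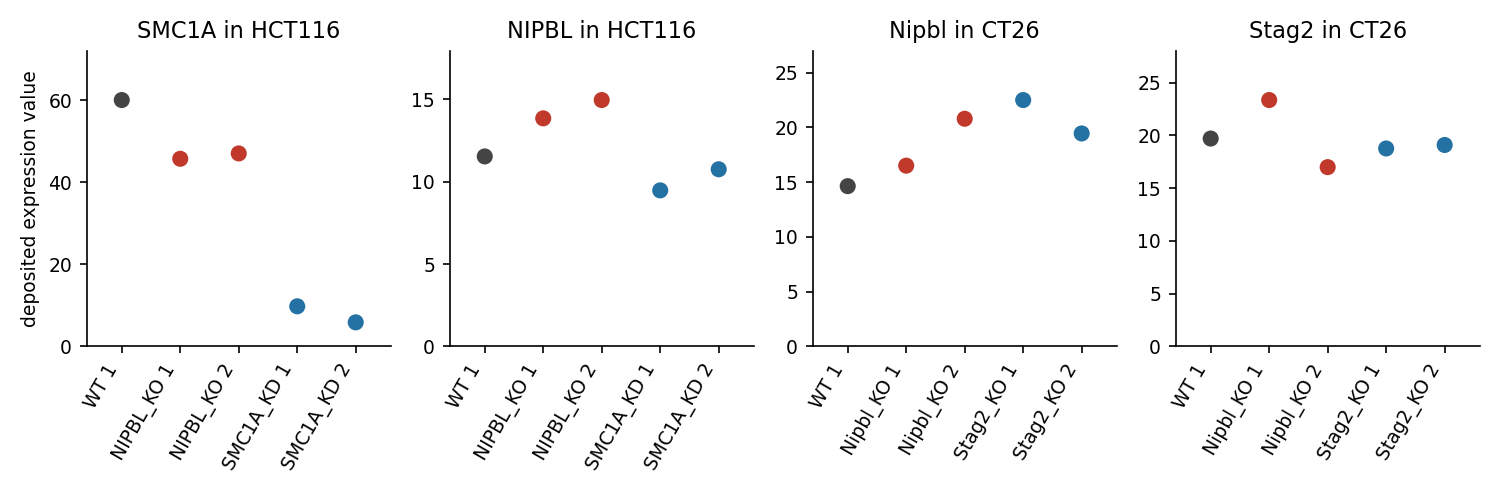
Deposited expression value (normalized signal, linear axis from 0) of SMC1A and NIPBL in the 5 HCT116 libraries and of Nipbl and Stag2 in the 5 CT26 libraries, 1 point per library, grey for wild type. SMC1A is at 60 in wild type and at 9.78 and 5.88 in its knockdown, while NIPBL, Nipbl and Stag2 in the libraries labelled as their knockouts lie at 13.8 and 14.9, 16.5 and 20.8, and 18.8 and 19.1.

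In HCT116, the libraries labelled NIPBL knockout had antiviral genes, those that interferons switch on, far above wild type. Of 30 measured interferon-stimulated genes, 29 were higher, with a median log2 fold change of 2.15, and the list rose (camera adjusted p = 2.27e-15, and adjusted p = 0.743 with an estimated correlation). BST2, a membrane protein that tethers budding viruses, read 0.33 in wild type against 209 and 235 (7.39 ± 1.50 on the log2 scale). IRF9, part of the transcription factor that interferon signalling activates, read 6.33 against 57.2 and 47.5 (2.86 ± 0.60). Both passed when adjusted over the list alone (adjusted p = 0.0454 for each) and not over all genes. IFI27, IFI6 and OAS1 were 8.42, 5.92 and 4.93 above wild type in replicate 1 and 8.96, 6.48 and 5.28 in replicate 2. The one lower member was UBA7, which activates the ubiquitin-like protein ISG15, at -0.13 and -0.22.

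Genes that cut and display peptides on MHC class I moved the same way. Of 19 members 18 were higher, median 1.04, and the list rose (adjusted p = 2.52e-11, and adjusted p = 0.743 with an estimated correlation). PSME2, an activator of the proteasome, read 94.2 in wild type and 267 and 274 in the knockout (1.51 ± 0.26), and PSMB9, an immunoproteasome subunit, 6.3 against 65.9 and 42.5 (2.88 ± 0.59). They passed when adjusted over the list alone (adjusted p = 0.023 and 0.0264), as did ERAP1 and PSME1. Genes of nucleic acid sensing in the cytosol (12 of 14 higher, median 0.50, adjusted p = 0.00159) and ligands of immune checkpoints (9 of 10, median 0.63, adjusted p = 0.00712) also rose as lists, each with adjusted p = 0.743 with an estimated correlation. The sensing list shares DDX58 and IFIH1 with the interferon list. Of the leukocyte markers, PTPRC, LAPTM5 and TYROBP were at most 0.17 in all HCT116 libraries, while CD68 read 5.3 in wild type and 3.76 and 10.6 in the knockout, ITGAM 0.13 against 0.22 and 1.46, and CORO1A 7.03 against 5.22 and 3.54.

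Genes of growth and DNA copying were lower. All 26 members of the list of MYC targets and ribosome biogenesis lay below wild type (median -0.57, adjusted p = 5.13e-13), as did 31 of 34 DNA replication genes (median -0.48, adjusted p = 2.7e-06) and 21 of 25 genes of homologous recombination (median -0.33, adjusted p = 0.0344). With an estimated correlation the adjusted p was 0.743, 0.743 and 0.844. Epithelial genes (22 of 27 higher, median 0.51, adjusted p = 1.29e-05), cholesterol biosynthesis (20 of 25, median 0.21, adjusted p = 0.00274), p53 targets (19 of 28, median 0.31, adjusted p = 0.0209) and immediate early genes (19 of 26, median 0.25, adjusted p = 0.0209) rose, each with adjusted p = 0.743 with an estimated correlation. CCNG2, a cyclin linked to cell cycle arrest, read 4.12 in wild type against 20.9 and 23.3 (2.17 ± 0.28). TM7SF2, a sterol reductase of cholesterol synthesis, read 10.7 against 52.5 and 43.2 (2.05 ± 0.28). Both passed when adjusted over the list alone (adjusted p = 0.00711 and 0.00854). So did 2 Wnt targets, DKK1, a secreted Wnt inhibitor, at 272 against 572 and 587.6 (1.09 ± 0.23), and EPHB3, a receptor of ephrins, at 6.28 against 15.9 and 14.7 (1.16 ± 0.28), with adjusted p = 0.0478 for each.

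The lists not called had medians of 0.38 for the mesenchymal side of the epithelial-mesenchymal transition, -0.32 for HOX genes, 0.22 for NF-kB targets, -0.23 for mismatch and base excision repair, -0.22 for the unfolded protein response, -0.15 for Wnt targets, -0.13 for cohesin genes, -0.06 for mitosis and -0.04 for oxidative phosphorylation (adjusted p = 0.053 to 0.991). Mitochondrial mRNAs and the hypoxia list had medians of 0.00. In replicates 1 and 2 mesenchymal genes were 0.20 and 0.69 and HOX genes -0.11 and -0.45, and without replicate 1 both were called (adjusted p = 0.0035 and 0.000288), as were Wnt targets (0.0429). Mesenchymal genes were also called without SMC1A knockdown replicate 1 or 2 (0.0405 and 0.0415), with a filter at a mean of 5 (0.0373) and with only the 2 groups compared (0.0432). Only COL1A1, COL6A1, COL6A2 and FBLN1 of the fibroblast markers were measured, too few for a test, with medians of 0.91 and 0.38 in the 2 knockout libraries, beside the mesenchymal list that COL1A1 belongs to.

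No single gene passed over all 12211 tested: limma called 0, with 731 at an unadjusted p under 0.05 (5.99%, 414 higher and 317 lower). The 5 genes with the smallest p, none of which passed (adjusted p = 0.73 for each), were CCNG2, TM7SF2, HAS3, DPEP1 and PPARG. HAS3, an enzyme that makes hyaluronan, read 91.9 in wild type against 8.48 and 5.85 (-3.53 ± 0.38). DPEP1, a membrane dipeptidase, read 54.8 against 1.96 and 3.11 (-4.00 ± 0.48), and PPARG, a nuclear receptor of lipid metabolism, 45.5 against 5.16 and 4.07 (-3.06 ± 0.39). The count moved with the libraries used, as limma called 20 genes without SMC1A knockdown replicate 1, 19 without replicate 2 and 21 with only the 2 groups compared. The p53 and immediate early calls were lost without NIPBL knockout replicate 2 (adjusted p = 0.319 and 0.387), the homologous recombination call without replicate 1 (0.121), and these together with the checkpoint ligands without the filter (0.0609 to 0.116). With a filter at a mean of 5 the homologous recombination and immediate early lists missed the threshold (0.0534 for each). In replicates 1 and 2 p53 targets had medians of 0.15 and 0.44, and cholesterol biosynthesis 0.21 and 0.36.

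One chromosome region stood out in a single library, a pattern picked after the values were seen, in windows of 20 Mb. In the library labelled NIPBL knockout replicate 1, 96.9% of the 32 genes measured between positions 100089015 and 114337626 of chromosome 13 were lower than in wild type, with a median log2 difference of -0.92. The other 3 perturbed libraries had medians of -0.01, 0.04 and -0.10 there. These limits are those of the window, and lower values also lie before it. Every measured gene from TGDS, a sugar dehydratase starting at 94574051, to ZIC2 at 99981772 was lower in this library. The differences ran from -0.19 in TM9SF2, a membrane protein, to -1.41 in IPO5. The measured gene before TGDS, NDFIP2, starts at 79481124 and was at -0.25, so where the lower stretch starts is not sharp. TFDP1, a partner of E2F factors in the cell cycle, read 179 in wild type and 74.3 in this library, and CUL4A, a scaffold of a ubiquitin ligase, 73 and 38.2. EFNB2, a ligand of ephrin receptors, was lower in both replicates, at 1.13 and 3.75 against 19. This library is 1 of the 2 behind each NIPBL knockout value above.

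**Figure D2:**
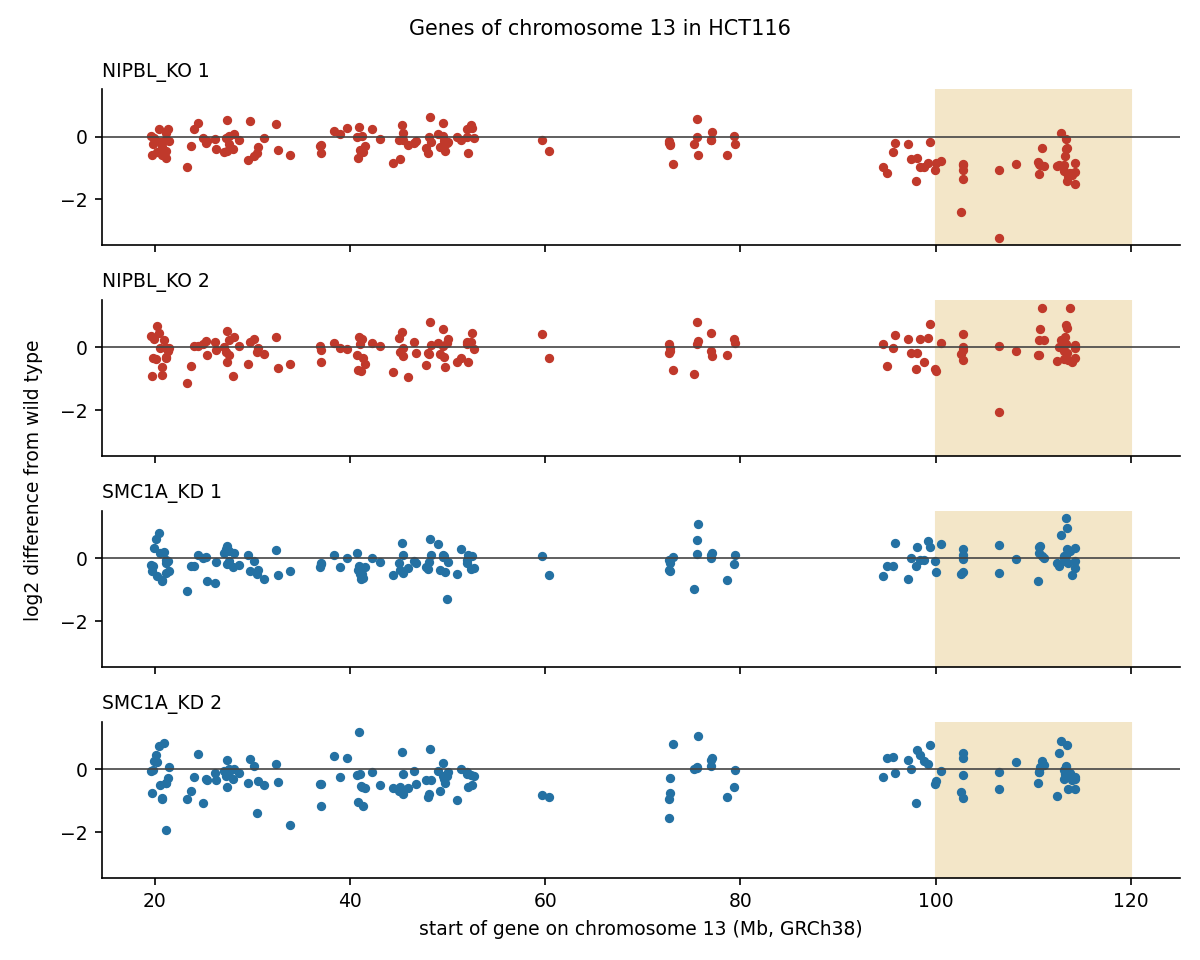
Log2 difference from wild type of each measured gene of chromosome 13 against its start position (Mb, GRCh38), 1 panel per perturbed HCT116 library, with the window from 100 to 120 Mb shaded. In the library labelled NIPBL knockout replicate 1 the shaded genes have a median of -0.92, in the others -0.01, 0.04 and -0.10.

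After SMC1A knockdown in HCT116, the genes of DNA copying, cell division and growth were lower. All 34 DNA replication genes (median -0.89, adjusted p = 5.12e-14), all 30 mitosis genes (median -0.70, adjusted p = 3.37e-08) and all 26 genes of MYC targets and ribosome biogenesis (median -0.58, adjusted p = 1.62e-11) lay below wild type, and the lists fell, each with adjusted p = 0.544 with an estimated correlation. Homologous recombination (23 of 25 lower, median -0.74, adjusted p = 9.2e-07) and the cohesin genes (15 of 19, SMC1A among them, median -0.28, adjusted p = 0.0272) fell with the same estimated-correlation value, adjusted p = 0.544. Mismatch and base excision repair (19 of 22, median -0.44, adjusted p = 0.00313) and oxidative phosphorylation (24 of 28, median -0.16, adjusted p = 0.0266) fell too, with adjusted p = 0.585 and 0.592 with an estimated correlation.

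The knockdown libraries lie apart from each other, and the gene groups move with that. Across tested genes, which are not independent replicates, the correlation with wild type is 0.974 for replicate 1 and 0.939 for replicate 2. The share of mitochondrial transcripts in the column total was 12.8% in replicate 2 and 10.4 to 11.3% in the other HCT116 libraries. It is a share of the authors' normalized values and not of reads, which limits it as a sign of RNA quality. DNA replication was -0.46 in replicate 1 and -1.32 in replicate 2, and mitosis -0.16 and -1.19. Homologous recombination was -0.27 and -1.24, mismatch repair -0.17 and -0.70, cohesin genes -0.13 and -0.41, and oxidative phosphorylation -0.05 and -0.26. Interferon-stimulated genes stood at 0.23 and 2.57: IFI27 was 0.47 and 7.58 above wild type, and OAS1 0.20 and 5.97. With 29 of 30 members higher (median 1.54) that list rose (adjusted p = 3.37e-08, and adjusted p = 0.544 with an estimated correlation), and MHC class I genes rose with it (16 of 19, median 0.62, adjusted p = 0.000383, and adjusted p = 0.544 with an estimated correlation), at 0.31 and 0.93.

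Sterol synthesis, mesenchymal and immediate early genes were higher. Cholesterol biosynthesis (22 of 25, median 0.53, adjusted p = 1.23e-07), immediate early genes (22 of 26, median 0.63, adjusted p = 7.42e-07), epithelial genes (23 of 27, median 0.57, adjusted p = 3.31e-06), mesenchymal genes (13 of 13, median 0.77, adjusted p = 8.47e-06), checkpoint ligands (9 of 10, median 0.65, adjusted p = 0.00313) and hypoxia and glycolysis (20 of 29, median 0.30, adjusted p = 0.00897) rose, each with adjusted p = 0.544 with an estimated correlation. The p53 targets rose as well (19 of 28, median 0.25, adjusted p = 0.0167, and adjusted p = 0.585 with an estimated correlation). The libraries differ in size here too, replicate 1 against replicate 2: cholesterol biosynthesis 0.30 and 0.76, immediate early genes 0.40 and 0.76, epithelial genes 0.32 and 1.03, mesenchymal genes 0.35 and 1.05, checkpoint ligands 0.29 and 1.22, hypoxia 0.27 and 0.05, and p53 targets -0.07 and 0.59. LOXL2, which crosslinks collagen, read 14.7 in wild type against 49.2 and 39 (1.51 ± 0.27), and COL1A1, a collagen chain, 22.3 against 48.7 and 67.2 (1.32 ± 0.29). NDRG1, a stress-induced gene, read 30.1 against 92.2 and 139 (1.87 ± 0.37), and ALDOC, a glycolytic aldolase, 16.8 against 71.2 and 54.1 (1.83 ± 0.31). These 4 passed when adjusted over the list alone (adjusted p = 0.0176, 0.0229, 0.0334 and 0.0292), as did CCNG2 (1.74 ± 0.28, adjusted p = 0.0238), TM7SF2 (1.59 ± 0.28, 0.0339) and DKK1 (1.12 ± 0.23, 0.0485). Fibroblast markers had medians of 0.59 and 0.97 in the 2 knockdown libraries, beside the mesenchymal list. Not called were the unfolded protein response (median 0.21), NF-kB targets (0.29), mitochondrial mRNAs (0.07), Wnt targets (0.01), HOX genes (-0.18) and nucleic acid sensing (0.27), with adjusted p = 0.0648 to 0.331. Replicates 1 and 2 differed for NF-kB targets (-0.02 and 0.60), Wnt targets (-0.17 and 0.35), nucleic acid sensing (0.03 and 0.38) and mitochondrial mRNAs (0.00 and 0.14), and without replicate 1 these lists were called (adjusted p = 0.012, 0.0204, 0.0253 and 0.00178). The unfolded protein response was called with quantile normalization of the tested genes (0.0483).

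Over all genes limma called 0 of 12211, with 879 at an unadjusted p under 0.05 (7.2%, 508 higher and 371 lower). The 5 smallest p belonged to SMC1A, CCNG2, MT1E, HIST2H4A and F8A2, none of which passed (adjusted p = 0.651 for each). MT1E, a metal-binding metallothionein, read 587.6 in wild type against 223 and 222 (-1.40 ± 0.21). HIST2H4A, one of many near-identical histone H4 genes, read 2.9 against 13.6 and 17.9 (2.09 ± 0.35). F8A2, one of several near-identical copies, was listed at 0 in wild type and at 3.55 and 5.97. Without SMC1A knockdown replicate 1 limma called 42 genes, 40 of them higher. Without replicate 2, which leaves the library nearer to wild type, 10 of the 16 lists stayed called: p53 targets, oxidative phosphorylation, mismatch repair, checkpoint ligands, cohesin and epithelial genes were lost (adjusted p = 0.0567 to 0.958, p53 targets with the direction turned), while hypoxia was lost without replicate 1 (0.07), MHC class I with 1 row per symbol (0.0613), and mesenchymal genes and checkpoint ligands without the filter (0.0736 and 0.14).

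**Figure D3:**
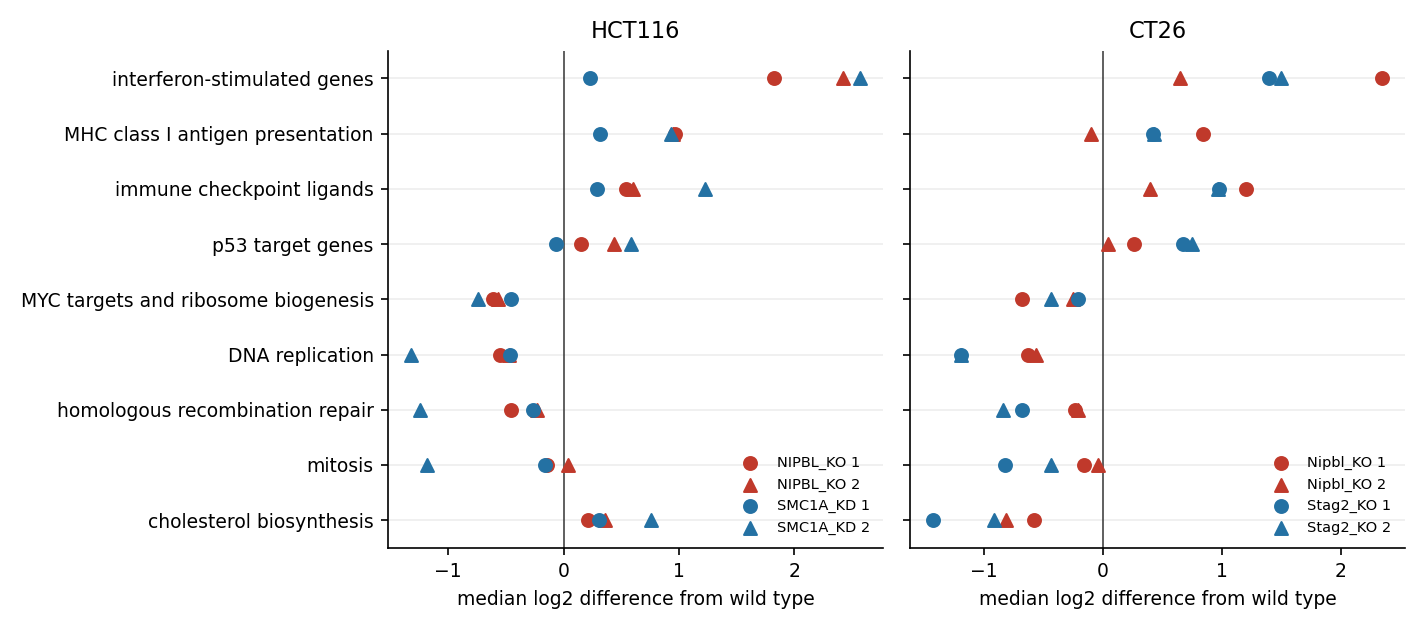
Median log2 difference from wild type (horizontal axis) of the members of 9 gene lists in each perturbed library of HCT116 (left) and CT26 (right), circles for replicate 1 and triangles for replicate 2. DNA replication lies below 0 in all 8 libraries (-0.46 to -1.32), and cholesterol biosynthesis lies above 0 in HCT116 (0.21 to 0.76) and below it in CT26 (-0.58 to -1.43).

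Set directly against the SMC1A knockdown, the libraries labelled NIPBL knockout had cell division genes higher and DPEP1 much lower. All 30 mitosis genes were higher (median 0.59, adjusted p = 1.51e-10), as were 32 of 34 DNA replication genes (median 0.41, adjusted p = 7.41e-06). So were 23 of 25 genes of homologous recombination (0.36, 0.000197), 18 of 19 MHC class I genes (0.39, 0.000108), 27 of 30 interferon-stimulated genes (0.61, 0.000849) and 13 of 14 genes of nucleic acid sensing (0.52, 0.00169). Cohesin genes (12 of 19, 0.25), mismatch repair (18 of 22, 0.21) and oxidative phosphorylation (20 of 28, 0.15) were higher with adjusted p = 0.00735 for each. Lower were the unfolded protein response (20 of 25, -0.46, 0.000409), mesenchymal genes (12 of 13, -0.46, 0.000296), immediate early genes (22 of 26, -0.34, 0.000197), cholesterol biosynthesis (18 of 25, -0.22, 0.00605) and Wnt targets (12 of 17, -0.21, 0.0279). All 14 lists had adjusted p = 0.69 with an estimated correlation. The other lists had medians between -0.15 (hypoxia) and 0.06 (p53 targets).

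Limma called 0 of 12211 genes here, with 699 at an unadjusted p under 0.05 (5.72%, 283 higher and 416 lower). The 5 smallest p, none passing, were those of DPEP1 (-4.83 ± 0.39, adjusted p = 0.195), SMC1A (2.46 ± 0.27, 0.638), and PPARG (-2.54 ± 0.32), VCAN and F8A2 (0.661 for each). VCAN, a proteoglycan of the matrix, read 1.56 and 0.14 in the knockout against 15.9 and 39.8 in the knockdown (-3.94 ± 0.55), and F8A2 was listed at 0 in the knockout. Adjusted over the list alone, SMC1A (adjusted p = 0.00199), PSME2 (1.47 ± 0.22, 0.00915), LIF, a cytokine (1.15 ± 0.28, 0.0485), ICAM1, an adhesion molecule (-1.58 ± 0.35, 0.0485) and CHAC1, which degrades glutathione (-1.20 ± 0.22, 0.0388) passed. Several of these list calls rest on 1 knockdown library: without replicate 1 the interferon list lay lower in the knockout instead of higher (adjusted p = 3e-05), MHC class I and nucleic acid sensing were lost (0.581 and 0.555), and limma called 2 genes. Without replicate 2 limma called 10 genes, 6 lists were called and 10 of the 14 calls were lost, among them mitosis (0.151), DNA replication (0.792), homologous recombination (0.723) and mismatch repair (0.905), the last 3 with the direction turned. Without NIPBL knockout replicate 1, mismatch repair, mesenchymal genes, cholesterol biosynthesis, immediate early genes and oxidative phosphorylation were lost (0.055 to 0.207), without replicate 2 cohesin genes and Wnt targets (0.13 and 0.109), and without the filter Wnt targets (0.44). Lists gained a call as well: epithelial genes and p53 targets lay lower in the knockout without SMC1A knockdown replicate 1 (1.61e-07 and 0.00635) and higher without replicate 2 (8.94e-07 and 0.00577). Without replicate 1 checkpoint ligands, NF-kB targets, HOX genes and mitochondrial mRNAs were called lower (0.00635, 0.043, 0.0301 and 1.62e-05). Without NIPBL knockout replicate 1 HOX genes and mitochondrial mRNAs were called (0.00112 and 0.0372), the latter also with a filter at a mean of 5 (0.0384), and without replicate 2 hypoxia (0.0359).

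The NIPBL knockout and SMC1A knockdown had 187 genes higher and 93 lower than wild type in both at an unadjusted p under 0.05, and 0 were called by limma in both. Both are measured from the same wild-type library, and simulated unchanged groups sharing 1 wild type gave means of 105 higher and 105 lower (at most 133 and 129). Only the genes higher in both exceed that level. The simulated genes varied independently of each other, while genes of a list may move together. The data also had more genes at that threshold, 731 and 879 where 611 are expected with no effect, more of them higher than lower. The excess is therefore not shown to be a shared response. CCNG2 and TM7SF2 were among the 5 genes of smallest p in the first comparison, and CCNG2 also in the second. Across genes, which are not independent replicates, the fold changes correlated at r = 0.681 (Spearman correlation 0.678), where the simulations gave 0.666. The covariance was 0.168 against 0.0918 in the simulations, and the share of genes with the same sign 76% against 73.2%. The simulations assume that the wild type varies like the perturbed libraries, which 1 library cannot show.

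In CT26, the libraries labelled Nipbl knockout likewise had interferon-stimulated genes above wild type, while sterol synthesis lay below it. Of 33 interferon-stimulated genes 32 were higher (median 1.50) and the list rose (adjusted p = 2.73e-22, and adjusted p = 0.423 with an estimated correlation). The 2 knockout libraries lie further from each other than from wild type. Across tested genes, which are not independent replicates, they correlated at 0.938 with each other and at 0.951 and 0.964 with wild type. Only 59.2% of genes lay on the same side of wild type in both. In the interferon list they differ in size: the median was 2.35 in replicate 1 and 0.65 in replicate 2. Rsad2, an antiviral enzyme, was 4.89 and 0.94 above wild type, Isg15, a ubiquitin-like modifier, 2.95 and 1.51, and the one lower member was Ifi27. Checkpoint ligands (9 of 9, median 0.78, adjusted p = 2.78e-06) rose, with adjusted p = 0.423 with an estimated correlation. The list's median was 1.21 in replicate 1 and 0.40 in replicate 2. Cd274, which encodes PD-L1, was 2.67 and 0.58 above wild type. MHC class I genes (19 of 19, median 0.38, adjusted p = 4.47e-05), nucleic acid sensing (14 of 18, 0.48, 0.00115) and NF-kB targets (13 of 16, 0.39, 0.00772) rose too, with adjusted p = 0.48, 0.463 and 0.423 with an estimated correlation. Their medians were 0.84, 0.98 and 0.61 in replicate 1 and -0.10, 0.11 and 0.15 in replicate 2, where 10 of the 19 MHC class I genes lay below wild type. Leukocyte markers moved with replicate 1: their median over Cd14, Lyz2, Cd68 and Coro1a was 1.11 there and -0.03 in replicate 2. Cd68 read 2.35 in wild type, 31 in replicate 1 and 1.68 in replicate 2, while Ptprc, Laptm5 and Tyrobp were at most 0.02 in these libraries.

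Of 34 DNA replication genes all were lower (median -0.58, adjusted p = 4.57e-16), as were 21 of 23 genes of cholesterol biosynthesis (-0.70, 8.68e-12), all 26 of MYC targets and ribosome biogenesis (-0.48, 2.99e-09), 18 of 22 of mismatch and base excision repair (-0.36, 0.00138) and 20 of 25 of homologous recombination (-0.20, 0.0024). With an estimated correlation the adjusted p was 0.423 for these lists and 0.463 for MYC targets. The MYC list had medians of -0.68 in replicate 1 and -0.25 in replicate 2, with an adjusted p of 0.00508 without replicate 1. Mitochondrial mRNAs, a sign of RNA quality, fell (10 of 13, -0.23, 0.00772), with medians of -0.29 and -0.18 in the 2 libraries, and so did clustered protocadherins, adhesion proteins of neurons (5 of 5, -0.24, 0.0291, with -0.05 and -0.70 in replicates 1 and 2), both with adjusted p = 0.423 with an estimated correlation. Wnt targets (-0.16), p53 targets (0.23), hypoxia (-0.29), mitosis (-0.09), fibroblast markers (-0.29), oxidative phosphorylation (0.10), epithelial genes (0.28), the unfolded protein response (-0.01), mesenchymal genes (-0.07), HOX genes (0.02), cohesin genes (-0.04) and immediate early genes (-0.03) were not called (adjusted p = 0.0634 to 0.892).

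Limma called 0 of 10510 genes, with 340 at an unadjusted p under 0.05 (3.24%, 179 higher and 161 lower), and 0 list members passed when adjusted over the list alone. The 5 smallest p, none passing, were those of Oplah, Slc1a2, Grem1, Arhgef5 and Banp. Oplah, an enzyme of glutathione turnover, read 55 in wild type against 2.36 and 3.43 (-3.86 ± 0.37, adjusted p = 0.253), and Grem1, a secreted inhibitor of BMPs, 28.5 against 3.92 and 2.46 (-2.84 ± 0.37, 0.513). Slc1a2, a glutamate transporter, read 13.4 against 0.04 and 0 (-3.82 ± 0.48, 0.513), and Arhgef5, a guanine nucleotide exchange factor, 4.36 against 0.02 and 0 (-2.41 ± 0.35, 0.797). Banp, a DNA-binding nuclear protein, read 6.16 against 30 and 24.2 (1.97 ± 0.30, 0.883). Without Nipbl knockout replicate 2 limma called 50 genes, 47 of them higher. Without replicate 1 the MHC class I, nucleic acid sensing and NF-kB calls were lost (adjusted p = 0.886, 0.263 and 0.215), and the protocadherin call without replicate 2 (0.272) or with quantile normalization of the tested genes (0.0825). Wnt targets and hypoxia were called, as lower, without Nipbl knockout replicate 1 (0.011 and 0.0191), without Stag2 knockout replicate 1 (0.0391 and 0.0308) or 2 (0.0396 and 0.0332) and with only the 2 groups compared (0.0397 and 0.0317). Fibroblast markers were called lower without Stag2 knockout replicate 1 or 2 (0.048 and 0.0473) and with a filter at a mean of 5 (0.0459), and p53 targets higher without Nipbl knockout replicate 2 (0.0235).

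**Figure D4:**
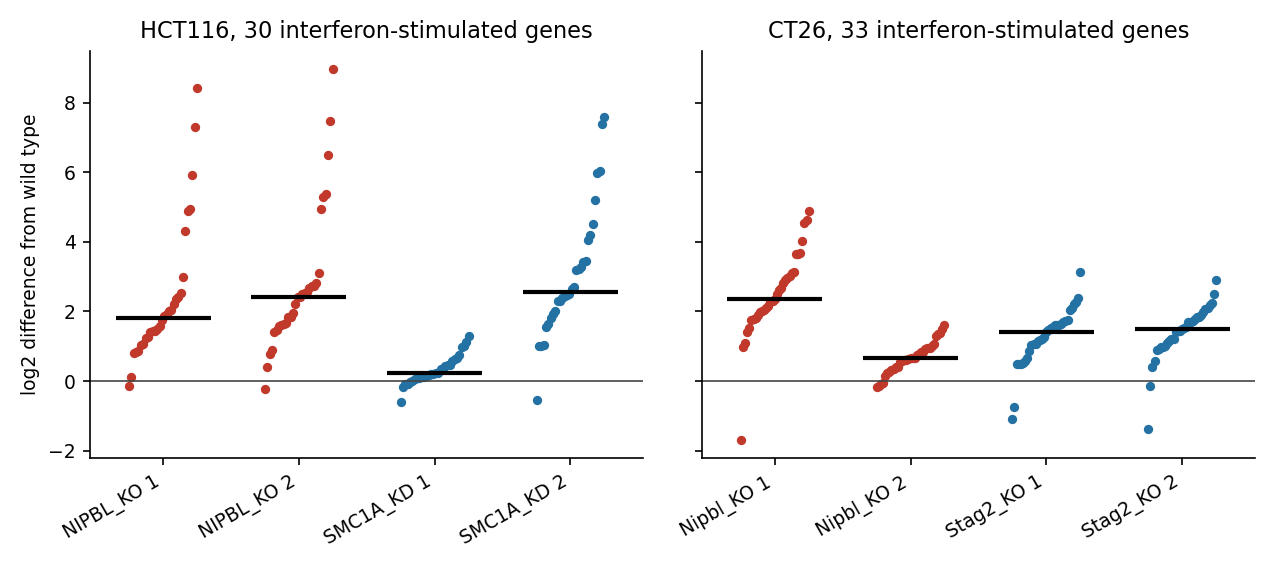
Log2 difference from wild type (vertical axis) of each of 30 interferon-stimulated genes in HCT116 (left) and 33 in CT26 (right), 1 point per gene, 1 column per perturbed library, bars at the medians. The medians are 1.82, 2.42, 0.23 and 2.57 in HCT116 and 2.35, 0.65, 1.40 and 1.49 in CT26.

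The libraries labelled Stag2 knockout had sterol synthesis and DNA replication down together. All 34 DNA replication genes were lower (median -1.18, adjusted p = 1.83e-22) and so were all 23 genes of cholesterol biosynthesis (-1.21, 3.52e-14), and both lists fell, with adjusted p = 0.29 and 0.432 with an estimated correlation. Adjusted over the list alone, 25 and 12 members passed. Mcm4 and Mcm7, parts of the helicase that opens DNA for copying, read 63.4 and 193 in wild type, 18.4 and 17.1, and 62.6 and 51.1 in the knockout (-1.78 ± 0.28 and -1.75 ± 0.29, adjusted p = 0.00803 for each). Acat2, which makes the precursor of the sterol pathway, read 99.8 against 11.8 and 11.5 (-2.99 ± 0.29, adjusted p = 0.000635), and Mvd, a later enzyme of it, 53.5 against 10.9 and 18.1 (-1.85 ± 0.37, 0.017). Homologous recombination (23 of 25 lower, -0.78, 8.51e-08), mitosis (28 of 30, -0.63, 9.15e-08), mismatch and base excision repair (18 of 22, -0.59, 8.35e-05), hypoxia (18 of 24, -0.56, 0.0025) and MYC targets (21 of 26, -0.26, 0.016) fell, with adjusted p = 0.29, 0.494, 0.347, 0.494 and 0.68 with an estimated correlation. Hypoxia had medians of -0.77 in replicate 1 and -0.33 in replicate 2, and MYC targets -0.21 and -0.44. Passing over the list alone were Brca2 and Rad54l, which act in strand exchange (-1.70 ± 0.31 and -1.43 ± 0.31, adjusted p = 0.025 and 0.0328). Lig1, a DNA ligase, Apex1, a nuclease of base excision, and Polb, a repair polymerase, passed as well (-1.50 ± 0.28, -1.45 ± 0.28 and 1.05 ± 0.30, adjusted p = 0.0174, 0.0174 and 0.0355).

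Stress and immune genes were higher. Interferon-stimulated genes (31 of 33, median 1.42, adjusted p = 1.53e-09, and adjusted p = 0.509 with an estimated correlation) had medians of 1.40 and 1.49 in the 2 libraries, with Usp18, which restrains interferon signalling, at 3.15 and 2.91. The p53 targets rose (19 of 24, 0.79, 1.12e-06, and adjusted p = 0.432 with an estimated correlation), 9 members higher and 1 lower when adjusted over the list alone. Gadd45a, induced by growth arrest, read 45.3 against 617 and 364 (3.36 ± 0.59) and Btg2, an inhibitor of proliferation, 3.47 against 15.9 and 21.4 (2.12 ± 0.35), with adjusted p = 0.00938 for each, while Polh, a polymerase that bypasses damage, read 21.4 against 9.26 and 9.14 (-1.13 ± 0.29, 0.023). The unfolded protein response rose (18 of 25, 0.32, 0.00138, and adjusted p = 0.494 with an estimated correlation). In it Ppp1r15a, which restores translation after stress, read 20 against 215 and 124 (2.97 ± 0.51) and Hspa5, a chaperone, 281 against 953 and 742 (1.58 ± 0.27), with adjusted p = 0.0102 over the list alone for each.

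Checkpoint ligands (8 of 9, 1.09, 0.000981), NF-kB targets (14 of 16, 0.36, 0.0195), protocadherins (4 of 5, 1.09, 0.0231) and immediate early genes (15 of 22, 0.27, 0.0273) rose, each with adjusted p = 0.494 with an estimated correlation. MHC class I genes (16 of 19, 0.47, 0.0312) and nucleic acid sensing (12 of 18, 0.35, 0.0467) rose with adjusted p = 0.68 and 0.663 with an estimated correlation. In replicates 1 and 2 nucleic acid sensing was 0.29 and 0.61, NF-kB targets 0.16 and 0.49, and immediate early genes 0.15 and 0.49. Cd80, a costimulatory ligand of T cells (2.48 ± 0.57), Csf1, a growth factor of macrophages (1.67 ± 0.35) and Snai2, a repressor of epithelial genes (1.46 ± 0.29) passed when adjusted over the list alone (adjusted p = 0.0354, 0.0354 and 0.038). Leukocyte markers had medians of 0.69 and 0.34 in these libraries, with Lyz2 at 0.48 in wild type and 6.1 and 25, and fibroblast markers -0.66 and 0.70. Not called were mitochondrial mRNAs (-0.21), cohesin genes (-0.08), Wnt targets (-0.15), mesenchymal genes (0.07), epithelial genes (0.10), HOX genes (0.00), oxidative phosphorylation (-0.01) and fibroblast markers (-0.01), with adjusted p = 0.115 to 0.924.

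Limma called 0 of 10510 genes, with 1242 at an unadjusted p under 0.05 (11.8%, 561 higher and 681 lower). The 5 smallest p, none passing, were those of Oplah (2.49 and 3.43 against 55 in wild type, -3.83 ± 0.37, adjusted p = 0.145), Acat2 (0.145), 4930486L24Rik (21.6 and 16.4 against 1.17, 3.19 ± 0.35, 0.15), Arhgef5 (41.4 and 53.9 against 4.36, 3.17 ± 0.35, 0.15) and Banp (35.4 and 38.4 against 6.16, 2.40 ± 0.30, 0.216). Without Nipbl knockout replicate 1 or 2 limma called 36 or 34 genes, and 31 with only the 2 groups compared. The calls of MYC targets, MHC class I, nucleic acid sensing, NF-kB targets and immediate early genes were lost without Stag2 knockout replicate 2 (adjusted p = 0.0911 to 0.261), the last 4 also without the filter (0.051 to 0.179), nucleic acid sensing with median-centred libraries (0.0565) and protocadherins with a pseudocount of 0.1 (0.107). Fibroblast markers were called higher without Stag2 knockout replicate 1 (0.0121).

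Between the Nipbl and Stag2 knockouts of CT26, limma called 2 of 10510 genes, both lower in the libraries labelled Nipbl knockout. Arhgef5 read 0.02 and 0 in the Nipbl knockout against 41.4 and 53.9 in the Stag2 knockout (-5.58 ± 0.29, adjusted p = 0.00438), and wild type, at 4.36, lies between them. Dppa4, a gene of pluripotent cells, was listed at 0 in both Nipbl knockout libraries and read 20.6 and 24 in the Stag2 knockout (adjusted p = 0.0116). Next by p, and not passing, were Clstn3, a synaptic adhesion protein, at 0.28 and 1 against 17 and 21.8 (-3.66 ± 0.34, adjusted p = 0.0656), Grem1 (-3.08 ± 0.30, 0.0656) and 6030419C18Rik (-3.48 ± 0.36, 0.0672). DNA replication (33 of 34 higher, median 0.53, adjusted p = 5.94e-10), mitosis (27 of 30, 0.54, 1.44e-06), cholesterol biosynthesis (23 of 23, 0.48, 3.24e-05), homologous recombination (22 of 25, 0.48, 5.83e-05), mismatch repair (16 of 22, 0.15, 0.0229) and hypoxia (18 of 24, 0.37, 0.0418) were higher in the Nipbl knockout, with adjusted p = 0.488, 0.647, 0.647, 0.488, 0.488 and 0.805 with an estimated correlation. Lower were p53 targets (19 of 24, -0.66, 2.25e-05), protocadherins (5 of 5, -1.76, 0.000251), the unfolded protein response (20 of 25, -0.37, 0.000251) and immediate early genes (15 of 22, -0.37, 0.0131), with adjusted p = 0.488, 0.488, 0.647 and 0.647 with an estimated correlation.

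Members that passed when adjusted over the list alone include Plk2 and Btg2 among p53 targets (-2.08 ± 0.32 and -1.89 ± 0.29, adjusted p = 0.00477 for each), with Sesn1 and Polh the other way (1.02 ± 0.30 and 0.80 ± 0.24, 0.0289 for each). Pcdhb17 and Pcdhb16 (-2.33 ± 0.36 and -2.29 ± 0.38, 0.00157 for each), Mcm4 and Tk1 (1.21 ± 0.23 and 1.64 ± 0.35, 0.0282 for each), and Acat2 and Dhcr7 (2.05 ± 0.24 and 1.31 ± 0.27, 0.0019 and 0.0268) passed in their lists. So did Psmb8 and H2-T23 of antigen presentation (3.78 ± 0.53 and 3.66 ± 0.87, 0.00441 and 0.0425), Ppp1r15a and Ddit3 (-2.24 ± 0.42 and -1.88 ± 0.47, 0.0311 and 0.047) with Sdf2l1 the other way (1.23 ± 0.28, 0.047), and Tnfsf9 and Cd80 (1.00 ± 0.28 and -1.79 ± 0.47, 0.0426 for each). Col3a1 (-2.02 ± 0.50, 0.0422) and Zeb2 (-1.03 ± 0.26, 0.0422) passed among mesenchymal genes, and Col3a1 with Dcn (-2.01 ± 0.42, 0.017), Pdgfra (1.41 ± 0.46, 0.0451) and Col6a1 (-1.85 ± 0.65, 0.0451) among fibroblast markers. The lists not called had medians from -0.42 (fibroblast markers) and -0.20 (MYC targets) to 0.22 (interferon-stimulated genes) and 0.20 (checkpoint ligands).

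Without the filter, or without Stag2 knockout replicate 1 or 2, limma called 0 genes in this comparison: Arhgef5 then had an adjusted p of 0.194, 0.191 and 0.314, and Dppa4 of 0.194, 0.307 and 0.531. It called 105 genes without Nipbl knockout replicate 1, 58 without replicate 2, 17 with robust variance moderation and 4 with quantile normalization of the tested genes, and the hypoxia list call was lost without the filter (adjusted p = 0.129), without Nipbl knockout replicate 1 (0.332) and without Stag2 knockout replicate 1 (0.691). Mismatch repair and immediate early genes were lost without Nipbl knockout replicate 2 (0.0618 and 0.358) and without Stag2 knockout replicate 2 (0.0599 and 0.0705). The interferon list, whose Nipbl knockout libraries lie on both sides of the Stag2 knockout (2.35 and 0.65 against 1.40 and 1.49), was called lower without Nipbl knockout replicate 1 (1.02e-08) and higher without replicate 2 (5.13e-15). Checkpoint ligands were called lower without Nipbl knockout replicate 1 (0.0381), while without replicate 2 MHC class I and nucleic acid sensing were called higher and MYC targets lower (0.00154, 0.0046 and 0.00098). Without Stag2 knockout replicate 1 fibroblast markers were called lower (0.000212), and without replicate 2 MYC targets (0.0212).

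The Nipbl and Stag2 knockouts shared 91 genes higher and 97 lower than wild type at an unadjusted p under 0.05, with 0 called by limma in both. Simulated unchanged groups sharing 1 wild type gave means of 88.9 and 89.5 (at most 117 and 119), which this overlap did not exceed. The counts are not alike, however: 340 and 1242 genes were at that threshold in the data, where 525.5 are expected with no effect. The simulated genes also varied independently of each other. The overlap therefore does not decide whether the knockouts share a response. Oplah and Banp were among the 5 genes of smallest p in both, and Arhgef5 was so with opposite sides of wild type. Across genes, which are not independent replicates, the fold changes correlated at r = 0.542 (Spearman correlation 0.533), below the 0.667 of the simulations, and 68.9% had the same sign against 73.3%. The covariance was 0.154 against 0.114 in the simulations.

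Between the 2 species, the libraries labelled NIPBL knockout shared the direction of the interferon and growth lists and parted on cholesterol biosynthesis. Over matched members the interferon list had a median of 2.10 in HCT116 and 1.60 in CT26, DNA replication -0.48 and -0.58, and MYC targets -0.57 and -0.48, with no difference called between the lines for these lists (adjusted p = 0.15, 0.388 and 0.507). For the interferon list this rests on the libraries used. It was called higher in HCT116 without NIPBL knockout replicate 1, without Nipbl knockout replicate 1 or without either SMC1A knockdown library. The SMC1A knockdown does not enter the difference, and leaving out a library of it kept the median difference at 0.14. Over all libraries the list's median difference was 0.14, but 1.17 without Nipbl knockout replicate 1 of CT26 and -0.72 without replicate 2. Without NIPBL knockout replicate 1 or 2 of HCT116 it was 0.43 or -0.11. The MYC difference was -0.09, but -0.28 without Nipbl knockout replicate 1, where the list was called lower in HCT116, and 0.07 without replicate 2. Cholesterol biosynthesis had medians of 0.24 in HCT116 and -0.72 in CT26, 20 of 22 members higher in the HCT116 effect (median difference 1.06, adjusted p = 1.79e-15, and adjusted p = 0.501 with an estimated correlation). MHC class I genes (8 of 14, median difference 0.32, adjusted p = 0.0289) and hypoxia (14 of 24, 0.27, 0.0222) also differed, each with adjusted p = 0.905 with an estimated correlation. The MHC class I difference rests on Nipbl knockout replicate 2 of CT26: without it the median difference was 0.04 (adjusted p = 0.744), and without replicate 1 it was 1.00 (8.05e-05). Without NIPBL knockout replicate 2 of HCT116 the MHC class I and hypoxia differences missed the threshold (0.0655 for each), as hypoxia did without Nipbl knockout replicate 2 (0.102). Limma called 0 of 8898 matched genes for a difference, with 210 at an unadjusted p under 0.05, fewer than the 445 that chance gives. Fold changes correlated across genes at r = 0.257 (Spearman correlation 0.249), 0.224 without the interferon list, and r = 0.267 between SMC1A knockdown and Nipbl knockout. Without Nipbl knockout replicate 1 of CT26 the first correlation was 0.076.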

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

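The tests of the patterns in this part were chosen after the results were seen.

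The effect of the libraries labelled NIPBL knockout, measured from wild type, differed between HCT116 and CT26 in 3 gene lists, by a test of the difference itself over all 10 libraries. Which lists were called changed with the library left out. The interferon list, not called over all libraries but called higher in HCT116 without some single libraries, had a median difference of 0.14. It was 1.17 without Nipbl knockout replicate 1 of CT26 and -0.72 without replicate 2. Cholesterol biosynthesis was higher than wild type in HCT116 (median 0.24) and lower in CT26 (-0.72), a median difference of 1.06 over 22 matched genes, 20 of them in that direction (adjusted p = 1.79e-15). MHC class I antigen presentation was higher in both lines, 0.97 and 0.37, with a median difference of 0.32 and 8 of 14 genes in that direction (adjusted p = 0.0289). This difference rests on Nipbl knockout replicate 2, whose median over all 19 genes was -0.10 against 0.84 in replicate 1: without replicate 2 it was 0.04 (adjusted p = 0.744) and without replicate 1 it was 1.00 (8.05e-05), the range of adjusted p over the libraries left out. Hypoxia and glycolysis had 0.08 and -0.29, a median difference of 0.27 with 14 of 24 genes in that direction (adjusted p = 0.0222). It missed the threshold without NIPBL knockout replicate 2 of HCT116 (0.0655, as MHC class I did) and without Nipbl knockout replicate 2 of CT26 (0.102), over the libraries left out 0.00467 to 0.102. With an estimated correlation the adjusted p of these differences was 0.501, 0.905 and 0.905.

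The cholesterol genes were higher in both HCT116 knockout libraries (0.21 and 0.36) and lower in both CT26 ones (-0.58 and -0.81). An offset of the authors' normalization shared by genes of like expression is argued against: among 10000 random lists matched for expression, the list's median stood at percentile 99.6 in HCT116 and at 0 in CT26. The list was picked for its difference from other genes, and random lists do not carry any correlation among its members. The percentiles may therefore overstate how rare such a shift is. A different culture state of the 2 single wild-type libraries cannot be told apart from an effect of the perturbation, since each line has 1 wild type. Exchanging the wild type with each other library in both lines, 25 relabellings in all, gave an exact adjusted p of 0.93 (0.08 before adjustment, where 0.04 is the smallest possible), which decides nothing with so few relabellings. The other perturbed libraries, measured from the same wild types, went the same ways: Stag2 knockout -1.43 and -0.91 in CT26, SMC1A knockdown 0.30 and 0.76 in HCT116.

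Interferon-stimulated genes were above wild type in all 8 perturbed libraries, by medians of 0.23 to 2.57. Reads from leukocytes are argued against, since the pan-leukocyte transcripts PTPRC, LAPTM5 and TYROBP reached at most 0.17 in the perturbed libraries, although Cd68 read 31 in Nipbl knockout replicate 1 and CD68 10.6 in NIPBL knockout replicate 2. A wild-type library that stands apart is argued against as the whole cause where the libraries of a group differ by at least 0.5 of their rise: replicate 2 minus replicate 1 was 2.2 in the SMC1A knockdown (random lists -0.2 to 0.21) and -1.68 in the Nipbl knockout (random lists -0.16 to 0.26). In the NIPBL knockout (0.35, random lists -0.15 to 0.14) and the Stag2 knockout (0.12, random lists -0.15 to 0.14) the libraries differ by less than that, so their own agreement does not decide it. From the same HCT116 wild type, SMC1A knockdown replicate 1 lay at 0.23, against 1.82 and 2.42 in the NIPBL knockout. From that of CT26, Nipbl knockout replicate 2 lay at 0.65, against 1.40 and 1.49 in the Stag2 knockout. Each is 1 library, so how much of these rises a wild type that stands apart accounts for cannot be told. Variation between cultures that is unrelated to the perturbation cannot be told apart from an effect of cohesin loss, which stays open: the exact relabelling gave an adjusted p of 0.18, and 0.04 before adjustment, the smallest that 25 relabellings can give.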

How the results depend on the processing

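The alternatives chosen after the data were seen are the filter at a mean of 5, median-centred libraries, quantile normalization of the tested genes, robust variance moderation and 1 row per symbol. The alternatives on counts chosen beforehand (edgeR with TMM, RLE or library size, count filters, DESeq2 and voom) were not run, as the files hold no counts. Without depth, the counting precision of low values is unknown.

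Over the counts of genes and lists, the correlations, the targeted genes and the interferon list, 286 values under alternatives stayed as reported, 51 moved, 1 became called and 8 lost a call, all 8 of the interferon list with an estimated correlation or fry. Of 1048 values of the 79 called lists under the alternatives with the preset correlation, 62 lost the call and 1 turned direction while called. For the 30 named gene results, 396 values under alternatives were computed: 336 stayed, 54 became called, 6 lost their call and 0 reversed. Only 2 of these results were called as reported, Arhgef5 and Dppa4 between the Nipbl and Stag2 knockouts, and the 6 losses are theirs. Most values that stayed belong to genes not called in either setting.

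Genes called by limma, where the number moved: NIPBL knockout against wild type in HCT116 (0 as reported, 731 at an unadjusted p under 0.05) gave 21 with only the 2 groups compared, and 0 to 20 leaving out 1 library. SMC1A knockdown against wild type (0, 879 unadjusted) gave 0 to 42, and NIPBL knockout against SMC1A knockdown (0, 699 unadjusted) 0 to 10. Nipbl knockout against wild type in CT26 (0, 340 unadjusted) gave 0 to 50, and Stag2 knockout against wild type (0, 1242 unadjusted) 31 with only the 2 groups and 0 to 36. Nipbl against Stag2 knockout (2) gave 0 with no filter, 4 with quantile normalization, 17 with robust moderation and 0 to 105 leaving out 1 library. The highest counts came without SMC1A knockdown replicate 1 (20 and 42), SMC1A knockdown replicate 2 (10), Nipbl knockout replicate 2 (50) and Nipbl knockout replicate 1 (36 and 105). A library left alone in its group was assumed to vary like the other groups. The spreads pooled in each line were unequal. The SD of the log2 difference between the 2 libraries of a group was 0.457 in the NIPBL knockout and 0.584 in the SMC1A knockdown. It was 0.684 in the Nipbl knockout and 0.456 in the Stag2 knockout. These highest counts all came without a library of the group with the wider spread. Whether that is their cause was not tested.

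A block on the replicate number gave 2, 0 and 2 genes in the HCT116 comparisons and 7, 127 and 137 in CT26, but the numbers do not pair the libraries: deviations from the group mean correlated at 0.0015 and 0.0061 across genes.

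Gene lists called, in the order above (11, 16, 14, 12, 16 and 10 as reported): 0 in all 6 comparisons with an estimated correlation, 0, 0, 0, 2, 4 and 1 with the directional test of fry, and 0, 0, 0, 0, 8 and 5 with its mixed test. Leaving out 1 library gave 9 to 13, 10 to 19, 6 to 18, 11 to 15, 11 to 17 and 9 to 12. The interferon list had adjusted p = 0.743, 0.544, 0.423 and 0.509 with an estimated correlation and 0.906, 0.554, 0.635 and 0.561 with fry for the comparisons with wild type. With the preset correlation it was called under every alternative run, with ranges of 7.4e-38 to 7.07e-10, 1.04e-29 to 0.00196, 1.35e-45 to 9.13e-11 and 1.41e-19 to 2e-05. The cause of the difference between the tests was not tested.

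SMC1A in its knockdown ranged from -3.15 to -2.50 leaving out 1 library and passed without replicate 1. The correlation of the 2 perturbations across genes ranged from 0.527 to 0.647 in HCT116 (0.681 as reported) and 0.387 to 0.534 in CT26 (0.542). Between the lines, 1 gene was called with a pseudocount of 0.1 and 0 to 1 leaving out 1 library (0 as reported, 210 unadjusted), and the correlation ranged from 0.076 without Nipbl knockout replicate 1 to 0.323 without replicate 2 (0.257).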

Other observations

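The tests in this part were chosen after the results were seen. The prediction on weakly expressed genes was written before its test, but it names the chromosome 13 pattern, which was itself picked after the values were seen.

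In CT26 the measured leukocyte markers were all above wild type in Nipbl knockout replicate 1 and went both ways in the other libraries. Cd14, a receptor of myeloid cells, read 30 in wild type, 50.5 and 28.9 in the Nipbl knockout and 14.3 and 41.9 in the Stag2 knockout. Cd68, a lysosomal protein of macrophages, read 2.35 in wild type, 31 and 1.68 in the Nipbl knockout and 1.82 and 1.04 in the Stag2 knockout. Lyz2, a lysozyme, read 0.48, then 0.96 and 1.4, and 6.1 and 25. Coro1a, an actin-binding protein of blood cells, read 0.27, then 2.54 and 0.26, and 2.95 and 0.46.

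In HCT116 the 266 genes measured between 40 and 60 Mb of chromosome 19 had a median log2 difference from wild type of 0.34 in the library labelled NIPBL knockout replicate 1, against 0.12, 0.01 and 0.08 in the other 3 perturbed libraries.

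Genes at the end of chromosome 13 were lower in that same library. Noise confined to weakly expressed genes is argued against, as the 16 genes of the window with a mean of at least 20 had a median of -0.93. These genes are part of the window picked for its low median, which made a low value among them more likely. Chance among windows is argued against as well: with the genes shuffled over the windows, the lowest window of each shuffle had as low a median in 0 of 1000 shuffles, the lowest being -0.48. A candidate explanation is the loss of a chromosome segment in these cells. In the window 96.9% of the genes were lower, against at most 65.6% in the other perturbed libraries. The window was picked for its low median in this library, so that share follows largely from the choice and does not test the loss. DNA was not measured, so the loss stays a hypothesis. No biological explanation from the groups was tested, since the other library with this label had a median of -0.01.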
